A study of Homo sapiens with 4 samples.

How the data were processed

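RNA was sequenced from C4-2 cells, a castration-resistant prostate cancer line derived from LNCaP, after culture in RPMI medium (control) or in RPMI with β-hydroxybutyrate (BHB), a ketone body, at 50 mM for 3 days. Each group held 2 libraries, with replicates numbered 1 and 2 in the labels. Per the labels' protocols, RNA was isolated on RNeasy Plus columns and libraries were built from total RNA with a stranded kit from BGI.

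The authors deposited 1 table of raw counts for 59385 features with an exon length each, and no normalization was applied to these counts. HISAT2 2.2.1, featureCounts 2.0.3, edgeR and limma, with the builds GRCh38 and hg38, are named in the submitters' processing notes. The annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. No row without a gene name was found in the table.

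Features were placed on GENCODE release 29 (GRCh38) by name, or through their current symbol, with 39254 features placed (66.1%). Of the placed features, 59.4% had the same exon length as in that release, so the gene models of the deposited table differ in part, and coordinates are those of release 29. Another 19266 features carried clone-style names, which differ between releases and were not matched. Overlaps on opposite strands were found with bedtools 2.31.1. A noncoding feature with exons opposite the exons of a coding gene was called partnered (1376 features). A coding gene with no gene body on the other strand was called solitary (11108 features). Pairs with a summed mean of at least 20 counts were used to compare a noncoding feature with the coding gene opposite it. Density was the mean count per kilobase of the feature's own exon length in the table. It was first taken per kilobase of the overlap for the noncoding feature. That was changed after its result was seen, because it inflates the noncoding side, and it had put the noncoding density higher in 82.2% of pairs, against 67.5% as used here. For the correlation of densities, pairs were chosen by a mean of at least 20 counts in the noncoding feature alone, after a first version with the summed mean. The minority-strand index of a library was the median, over 263 pairs in which the noncoding feature had a mean of at least 100 counts, of the log2 ratio of the coding gene to the opposite noncoding feature.

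The total count per library lay between 2233711 and 2565080. Shares of a library are given with 95% Wilson intervals, and a count of 0 allows up to 3 counts of the total. Both cover counting error only, because reads without molecular identifiers are not independent molecules. Replicate libraries were checked for duplicates by a chi-square test of their counts. It gave 15.1 per degree of freedom for the controls and 2.59 for the BHB libraries, both above sampling noise, and each library was counted once.

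BHB and control libraries were compared with edgeR 4.0.16 in R 4.3.3, by filterByExpr with default settings, TMM scaling and the robust quasi-likelihood F-test, with Benjamini-Hochberg adjusted p (FDR) under 0.05 as the threshold. Fold changes are log2 of BHB over control with a standard error (SE) from the F statistic. CPM of single genes are TMM-scaled, while those of partnered features are relative to all counts in the library without a scaling factor. Before the data were examined, 41 gene lists were fixed, and those with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry (limma 3.58.1) were run beside it. Genes to name were fixed in the same way, among them EZH2, EED, SUZ12 and EZH1; 1 other gene fixed there is not reported here. To these were to be added the 10 strongest called genes per direction with a mean of at least 5 CPM and both BHB libraries beyond both controls, plus up to 4 called members of each primary list and up to 2 of each other list. The last 2 parts of the rule gave no gene, since no gene was called.

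The fit of partnered features on their own, the fit of clone-named features on their own and the fit of solitary coding genes on their own were chosen after the data were seen. So was the choice of partnered features to name, which applied the size rule above to called features with 1 opposite coding gene. Mitochondrial genes and the gene pairs that describe the strands were also chosen after their values were seen.

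On simulated counts with 200 changed genes, drawn with the library sizes, means and dispersions of these data, the whole-table fit of 9295 features recovered 40.9% of genes changed 4-fold, 1.49% of genes changed 2-fold and 0% of genes changed 1.5-fold. A run on 644 partnered features, also with 200 changed, recovered 98.5% of features changed 4-fold, 83.6% changed 2-fold and 53.7% changed 1.5-fold. Of the calls, 6.67% were false in the first and 2.48% in the second. The changed features were a far larger share of 644 than of 9295, which eases the threshold, so these rates cannot be compared between the runs. Features were drawn independently, without the shift between the controls that many coding genes share, so the rates need not hold for the real counts.

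Alternatives were DESeq2 size factors, upper-quartile scaling and total counts without scaling, all in edgeR; no filter beyond a total above 0, or at least 1 CPM in at least 2 libraries; the DESeq2 1.42.0 Wald test and limma-voom; a replicate block; and the removal of each library in turn. An FDR under 0.01 and a minimum fold of 1.5 were also tried for the counts of genes. Added later were the 3 fits by feature class and a fit with the minority-strand index as a covariate.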

Results

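Gene expression was measured by RNA sequencing in C4-2 prostate cancer cells cultured for 3 days in medium alone or with 50 mM BHB, the main circulating ketone body, with 2 libraries per group. The series is about ketones and EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2), in prostate cancer. The total count was 2565080 in control replicate 1, 2237634 in control replicate 2, 2272004 in BHB replicate 1 and 2233711 in BHB replicate 2. In the same order, 18218, 16169, 17747 and 17490 features had at least 1 count. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

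Many features opposite abundant genes held more counts than the abundant genes themselves. Counts listed under BEST1 were between 48822 and 54563 per library, while FTH1, the ferritin heavy chain gene on the other strand, had 65 to 429. MIF-AS1 averaged 10576.5 counts and MIF, a cytokine gene among the coding genes opposite it, 5.25. The reverse was also seen, as ENO1-AS1 averaged 179.25 counts and the glycolytic gene ENO1 588.75. Among 704 pairs of a noncoding feature and the coding gene opposite, the count per kilobase of exon was higher in the noncoding feature in 67.5%, with a median ratio of 6.24, and the plain count was higher in 57.1%. In the 5 pairs with a ribosomal protein, glycolytic or oxidative phosphorylation gene it was higher per kilobase in 1. MT-ND6, the one protein gene of the mitochondrial light strand, had 21.2 to 28.9 times the median count per kilobase of the 12 heavy-strand protein genes. The 30 tested cytosolic ribosomal protein genes had a median of 213 counts. Values below are therefore given as counts listed under a name.

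The control libraries differed from each other most in one class of features. Solitary coding genes held 8.91% of all counts in control replicate 1 (95% Wilson interval 8.87 to 8.94) and 4.44% in control replicate 2 (4.41 to 4.47), against 6.36% (6.33 to 6.39) and 6.43% (6.39 to 6.46) in BHB replicates 1 and 2. Smaller differences between control replicates 1 and 2 were seen in mitochondrial features (1.30% and 1.05%) and in features that were not placed (38.7% and 43.0%). The median log2 ratio of counts between the controls was 1.58 (SD 1.14) over 1364 solitary coding genes and 0.05 (SD 0.35) over 544 partnered noncoding features. Between the BHB libraries it was 0.01 (SD 0.52) and 0.03 (SD 0.31).

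**Figure D1:**
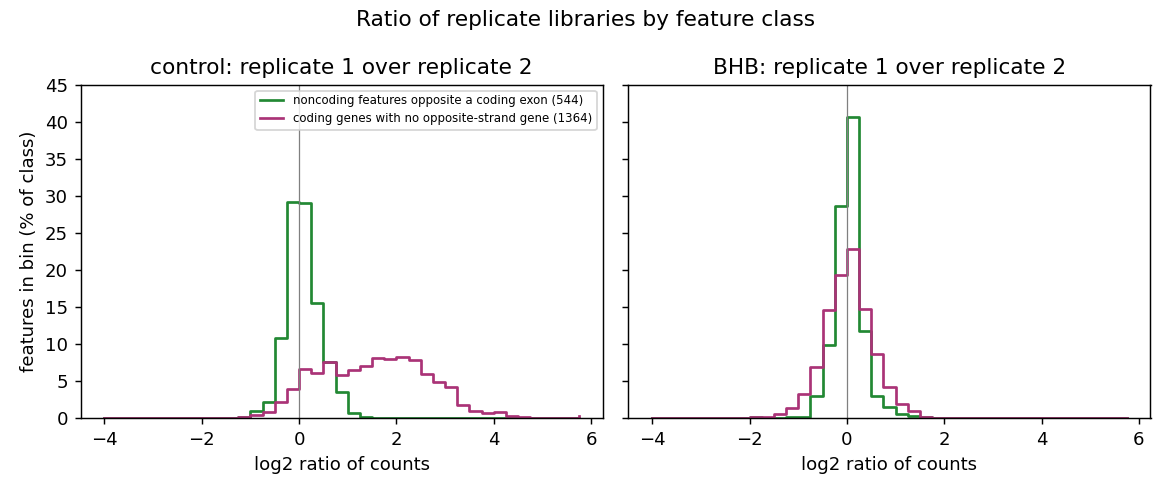
Histograms of the log2 ratio of counts of replicate 1 over replicate 2, for controls (left) and BHB libraries (right), as the percent of each class of features with a mean of at least 20 counts. The 1364 solitary coding genes have a median of 1.58 in the controls and 0.01 with BHB, while the 544 partnered noncoding features have medians of 0.05 and 0.03.

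The design asked whether BHB changes expression, with EZH2 named in the title. EZH2 (chromosome 7, 148807383 to 148884321) had 89 and 18 counts in the control libraries and 49 and 39 with BHB. This was 20.6 ± 16.2 CPM (SD, n = 2) in controls and 19.6 ± 2.87 CPM (SD, n = 2) with BHB, a log2 fold change of −0.09 (SE 0.58) that did not pass the edgeR test (adjusted p = 1.0). Both BHB values lay between the control values, as did the share of counts in solitary coding genes, the class that EZH2 belongs to. EZH2 therefore cannot be told apart from the difference between the controls in that class, and counts listed under it may not measure its RNA. The other PRC2 core genes gave no call either. EED (chromosome 11, 86244544 to 86278813), which binds the methylated histone tail, had a log2 fold change of 0.06 (SE 0.59). SUZ12 (chromosome 17, 31937018 to 32001045), a scaffold subunit, had −0.27 (SE 0.70). EZH1 (chromosome 17, 42700275 to 42745049), the related methyltransferase, had 12, 0, 6 and 4 counts in control replicates 1 and 2 and BHB replicates 1 and 2 and was too low to test. With these standard errors a change of their size was not detectable. Without control replicate 1 the log2 fold change of EZH2 was 1.08, and without control replicate 2 it was −0.67, and neither passed the edgeR test.

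**Figure D2:**
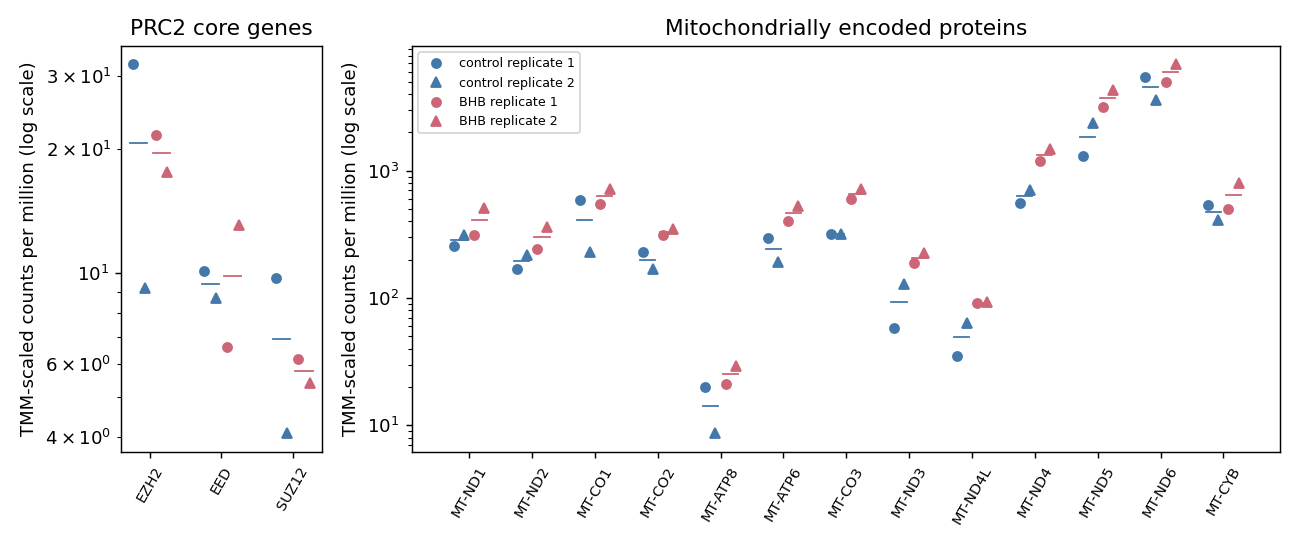
TMM-scaled CPM (log axis) of PRC2 core genes (left) and of the 13 mitochondrially encoded protein genes (right) in each library; circles are replicate 1, triangles replicate 2, blue control, red BHB, and bars group means of 2 libraries. EZH2 with BHB (21.6 and 17.5) lies between the controls (32.1 and 9.17), while MT-ND4 is at 562 and 709 in controls and 1188 and 1492 with BHB.

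Over the whole table, 0 features were higher and 0 lower with BHB among 9295 tested by the edgeR quasi-likelihood test, with or without a minimum log2 fold change of 1. At an unadjusted p under 0.05 there were 210 features, below the 464.75 that chance would give. DESeq2 called 0, with 138 at an unadjusted p under 0.05, and limma-voom called 0, with 238. With total counts and no scaling factor 0 were called too, but 534 had an unadjusted p under 0.05, above chance. The common dispersion was 0.113. Without control replicate 1 there were 582 features higher and 635 lower, and without control replicate 2 there were 1035 and 791. Of 384 features called in both of these fits, 228 had opposite signs.

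Mitochondrial features held 1.30% and 1.05% of counts in control replicates 1 and 2, and 1.61% and 2.17% in BHB replicates 1 and 2. Over all tested mitochondrial features the median log2 fold change was 0.70. The ribosomal RNA MT-RNR2 had 1.06 (SE 0.59), with BHB replicate 1 between the 2 controls. Tested transfer RNAs ran from −0.18 (SE 0.35) for MT-TE to 0.79 (SE 0.50) for MT-TC. A rise beyond the protein genes was thus not established. Mitochondrially encoded protein genes stood higher with BHB as a group. All 13 genes had a positive log2 fold change, from 0.39 to 1.14 with a median of 0.80. In 9 of them both BHB libraries lay above both controls. Genes of the mitochondrial genome are not independent of each other. The smallest change was that of MT-ND6 (SE 0.29), which held the most counts of the 13. Its BHB replicate 1, at 4987 CPM, lay between control replicates 1 and 2, at 5461 and 3577 CPM. The larger changes were thus in the 12 heavy-strand genes, whose median count per kilobase was far lower. MT-ND4 (positions 10760 to 12137 of the mitochondrial genome), a complex I subunit, had a log2 fold change of 1.08 (SE 0.26). MT-CO3 (9207 to 9990), a cytochrome c oxidase subunit, had 1.05 (SE 0.24), and MT-ND5 (12337 to 14148) had 3641 and 4621 counts in controls and 7134 and 9626 with BHB. None passed over all features, and 7 of the 13 passed adjusted over the list alone. It was the single list of 35 tested that passed camera (adjusted p = 1.5e-19), and the call was lost with an estimated correlation (p = 0.044, adjusted p = 1.0).

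None of the other lists passed camera, at adjusted p of 0.23 or more, and none of their members was called over all features or adjusted over the list alone. Counts listed under these genes may not measure their RNA, so the medians need not speak of the pathways named. The whole-table fit recovered 1.49% of simulated 2-fold changes, so the absence of called members says little about changes of that size. Median log2 fold changes are given here with the number of tested members. For the chromatin lists, PRC2 subunits had −0.09 (7), reported EZH2-repressed genes 0.23 (4), histone deacetylases 0.08 (6) and genes induced by histone deacetylase inhibition 0.04 (6). Androgen-activated genes had −0.20 (21), androgen-repressed genes 0.38 (3) and luminal keratins and epithelial markers 0.01 (9). In metabolism, ketone body metabolism and transport had −0.02 (6), glycolysis −0.54 (15), nuclear-encoded oxidative phosphorylation −0.39 (13), fatty acid synthesis −0.23 (11), fatty acid oxidation −0.35 (7) and cholesterol synthesis and uptake −0.13 (9). Among growth lists, DNA replication and S phase had −0.29 (21), mitosis −0.55 (18), cyclin-dependent kinase inhibitors −0.08 (4), MYC targets and ribosome biogenesis −0.08 (16), cytosolic ribosomal proteins −0.25 (30), and homologous recombination and Fanconi repair 0.0048 (8). Among stress lists, p53 targets had 0.30 (8), the integrated stress response −0.01 (17), endoplasmic reticulum chaperones −0.22 (12), the heat shock response −0.14 (9), NRF2 targets −0.18 (10), the hypoxia response −0.02 (7), hyperosmotic stress 0.20 (4), autophagy and lysosome −0.05 (10), immediate early genes 0.41 (5) and the BCL2 family −0.19 (4). The interferon response had −0.02 (3), class I antigen presentation 0.23 (3), NF-kB targets and inflammasome 0.51 (4) and mesenchymal markers 0.40 (3). Neuroendocrine markers, with 1 tested member, and replication-dependent histones, with 2, were not tested as lists and had medians of 0.19 and 0.12. The median differed in sign from the mean or from the camera direction for PRC2 subunits, both histone deacetylase lists, cholesterol synthesis, the integrated stress response, heat shock, hypoxia, class I antigen presentation, autophagy and luminal keratins. The direction of several lists turned with the control library: glycolysis passed camera as higher without control replicate 1 and as lower without control replicate 2, and so did cytosolic ribosomal proteins, NRF2 targets, the heat shock response, endoplasmic reticulum chaperones, androgen-activated genes and MYC targets.

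Counts listed under markers of other cell types were near 0, but genes such as MIF and SLC7A11 (mean of 2 counts) were too, so these values cannot show that a cell type was absent. The basal genes KRT5, KRT15, KRT6A and TP63, the fibroblast genes COL1A2, COL3A1, DCN and LUM, the endothelial genes CDH5, KDR and TEK, and the leukocyte genes PTPRC, CD3E, CD14 and LYZ had 0 counts in all 4 libraries. A count of 0 allows up to 1.17 to 1.34 CPM in these libraries. KRT14 averaged 2.5 counts, ITGA6 17.25, COL1A1 6.25, PDGFRB 0.5, PECAM1 1, and VWF 2.5, while CD68, a lysosomal gene, had 57 to 76. Nuclear-retained RNAs, listed in advance as a sign of RNA quality, had a median log2 fold change of 0.16 over 5 members (camera adjusted p = 0.55). Reads listed under these names may not come from the RNAs they name, so they cannot show RNA quality or that it was alike in both groups. In the order control replicates 1 and 2 and BHB replicates 1 and 2, MALAT1 had 74, 10, 38 and 43 counts and NEAT1 48, 7, 20 and 25. SNHG14 had 606, 683, 811 and 716, TUG1 26, 10, 21 and 10, and KCNQ1OT1 98, 100, 164 and 128.

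Partnered noncoding features, whose counts had a median log2 ratio near 0 between the controls, were tested on their own after the data were seen. Their p-values and SE rest on this small spread, which was known when the class was chosen, so both may be too small. In the planned fit of all features none of them was called. Among 644 features (common dispersion 0.0091), edgeR called 24 higher and 27 lower with BHB at FDR under 0.05. In 50 of the 51 both BHB libraries lay beyond both controls. The absolute log2 fold change had a median of 0.59, with 2 features higher (STARD13-AS and H1-12P) and 1 lower (HELLPAR) by at least 1. Without control replicate 1 the counts were 5 higher and 9 lower, without control replicate 2 they were 39 and 54, without BHB replicate 1 they were 9 and 15, and without BHB replicate 2 they were 1 and 3. The 4 features PCA3, HELLPAR, CBR3-AS1 and MIR762HG kept the call in each of these fits.

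Counts listed under a partnered feature may come from the coding gene opposite it, so the values below do not show which RNA changed. Of the features named in this and the next paragraph, only PCA3, CBR3-AS1 and MIR762HG kept the call without each library in turn. Higher with BHB were counts listed under PCA3 (chromosome 9, 76691980 to 76863307), a prostate-specific noncoding RNA opposite PRUNE2. They were 821 ± 111 CPM in controls and 1542 ± 151 CPM with BHB (SD, n = 2), a log2 fold change of 0.88 (SE 0.10, edgeR adjusted p = 3.5e-12). SLC7A11-AS1 (chromosome 4, 138057464 to 138178177) overlaps 865 exonic bases of SLC7A11, the cystine and glutamate antiporter gene, and had 150 and 188 counts in controls and 279 and 334 with BHB (log2 fold change 0.91, SE 0.17). TNFRSF10A-AS1, opposite a TRAIL death receptor gene, had a log2 fold change of 0.74 (SE 0.18). TBL1XR1-AS1, opposite a gene for a subunit of nuclear corepressor complexes, had 0.67 (SE 0.12). NCMAP-DT, opposite the calcineurin regulator gene RCAN3, had 0.98 (SE 0.18), and PDE6B-AS1, opposite PDE6B, had 0.98 (SE 0.23). STARD13-AS, opposite STARD13, rose most in log2 terms at 2.75 (SE 0.59), on 4 and 4 counts in controls and 22 and 31 with BHB. KCNQ1OT1, the imprinted RNA opposite KCNQ1, had 0.61 (SE 0.20). The pseudogenes ANKRD36BP1, opposite SFT2D2, and AHSA2P, opposite USP34, had 0.72 and 0.57, and reads of pseudogenes can be shared with their related copies.

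With the same limit, lower with BHB were counts listed under MIR762HG (chromosome 16, 30875222 to 30895220), opposite BCL7C, which encodes a subunit of SWI/SNF remodelling complexes. They were 104 ± 4.43 CPM in controls and 53.7 ± 2.49 CPM with BHB (SD, n = 2), a log2 fold change of −0.98 (SE 0.18). CBR3-AS1 (chromosome 21, 36131767 to 36175815), opposite the carbonyl reductase gene CBR3, had −0.95 (SE 0.17, edgeR adjusted p = 7.7e-06). TPM1-AS, opposite the tropomyosin gene TPM1, had −0.85 (SE 0.16). EXOSC10-AS1, opposite a gene for a nuclear exosome ribonuclease, had −0.85 (SE 0.19), and −0.43 without control replicate 1. ENO1-AS1 (chromosome 1, 8878835 to 8879894), opposite ENO1, which itself held more counts, had 248 and 194 counts in controls and 135 and 140 with BHB (log2 fold change −0.62, SE 0.18). H1-10-AS1, opposite the linker histone gene H1-10, had −0.63 (SE 0.11). SRI-AS1, opposite the gene of the calcium-binding protein sorcin, had −0.67 (SE 0.18), and −0.31 without control replicate 1. ODF2-AS1, opposite the centriolar gene ODF2, had −0.65 (SE 0.17). MORF4L2-AS1, opposite MORF4L2, had −0.71 (SE 0.21), and the pseudogene RHOXF1P3, opposite NKAP, had −0.59 (SE 0.15).

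**Figure D3:**
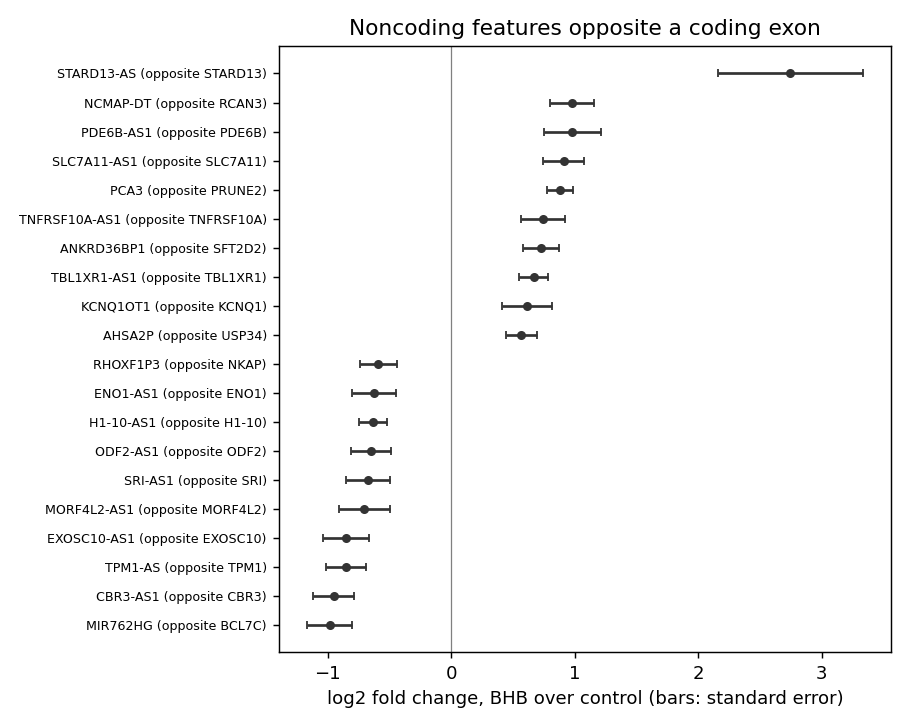
Log2 fold change of BHB over control (horizontal axis) with its standard error for the 10 partnered noncoding features with the highest and the 10 with the lowest values among called features with 1 opposite coding gene, a mean of at least 5 CPM and both BHB libraries beyond both controls, each labelled with that gene. Values run from −0.98 for MIR762HG to 2.75 for STARD13-AS.

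Clone-named features, which hold 38.6% to 42.9% of the counts per library, were not placed. Fitted on their own after the data were seen, 1874 of them gave 36 higher and 47 lower by edgeR, and these counts moved widely with the settings, to 114 and 122 with a replicate block and 3 and 6 with at least 1 CPM in 2 libraries. Examples chosen after their values were seen are AC018816.3, with 10 and 13 counts in controls and 60 and 45 with BHB, and AC142528.1, with 929 and 966 against 546 and 469. With total counts in place of TMM the split was 86 higher and 26 lower, which is 76.8% higher against 43.4%. Without BHB replicate 2, edgeR called 0 clone-named features, with 213 at an unadjusted p under 0.05, and 4 were higher and 8 lower without BHB replicate 1. The counts were 81 and 97 without control replicate 1 and 170 and 187 without control replicate 2.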

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

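The fits by feature class, every partnered-feature result and the minority-strand covariate were chosen after the data were seen; all other alternatives were chosen before the data were examined. Over the whole table the counts of 0 higher and 0 lower held under 3 other scalings, 2 other filters, DESeq2, limma-voom, the replicate block, an FDR under 0.01 and a minimum fold of 1.5. Leaving out 1 library at a time gave 0 to 1035 features higher and 0 to 791 lower, and 0 to 461 and 0 to 454 with a log2 fold change of at least 1. With a library left out of a group, the lone library is assumed to vary like the other group. With the minority-strand index as a covariate, 488 features were higher and 299 lower, of which 99 and 33 by a log2 fold change of at least 1. That fit leaves the spread to rest mainly on the BHB pair. Fitted on their own, partnered features gave 24 higher and 27 lower, clone-named features 36 and 47, and solitary coding genes 0 and 0 by edgeR, with 24 of these at an unadjusted p under 0.05. Members of the gene lists called were 0 in the main comparison, 0 to 123 without 1 library, and 34 with the covariate.

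EZH2 passed the threshold in none of its alternatives, with a lowest adjusted p of 0.083 without control replicate 1. Its log2 fold change turned positive with limma-voom (0.059), the replicate block (0.12) and the covariate (0.062); it ran from −0.67 to 1.08 without 1 library. EED turned negative with limma-voom (−0.026) and the block (−0.0039) and ran from −0.50 to 0.49 without 1 library. Without 1 library, SUZ12 ran from −0.71 to 0.49. The cause was not tested for single genes.

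Partnered features higher with BHB numbered 1 to 39 and lower 3 to 54 without 1 library. They were 56 and 48 with the covariate, 15 and 18 at an FDR under 0.01, and 1 (STARD13-AS) and 0 against a minimum fold of 1.5. All 51 kept their sign in every refit that gave them an adjusted p, which DESeq2 did for 48. In 50 of them both BHB libraries lay beyond both controls, so the kept sign was nearly fixed in advance. Without a minimum fold, 4 kept the call in every refit. The replicate block gave 31 higher and 35 lower. The correlation of replicate differences between groups was −0.02 over all features and 0.07 over partnered features, which gives no sign of pairing. With the block, however, the common dispersion fell from 0.0091 to 0.0056 in partnered features and from 0.0095 to 0.0073 in clone-named features. Over the whole table it was 0.113 without and 0.119 with the block. Pairing by the shared numbers therefore stays open. The whole table had no call to lose, and the block added none. Clone-named features went from 36 higher and 47 lower to 114 and 122 with the block, and to 247 called in all with the covariate. They fell to 3 and 6 with at least 1 CPM in at least 2 libraries, and were 53 and 72 without a filter, 31 and 54 by DESeq2, and 36 and 48 by limma-voom.

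The number of lists passing camera was 1 in the main comparison, 1 to 12 without 1 library, 3 with the covariate (with glycolysis and cytosolic ribosomal proteins lower), 0 with an estimated correlation and 0 with fry. The mitochondrial list, with a median log2 fold change of 0.80, lost its call with the estimated correlation and with fry, and its adjusted p ran from 1.4e-41 to 1.0 over the alternatives. The SE of EZH2 was 0.58 in the main fit and 0.30 with the covariate on the same counts.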

Other observations

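Among the tests below, those of the strands, of the mitochondrial list, of the minority-strand share, of sequencing depth, of a difference between the control cultures and of the densities across pairs were chosen, or had their measure redefined, only after the results were seen. The test of the fold changes across pairs was not.

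Several called partnered features lie opposite genes of the lists fixed before the data were examined. SLC7A11-AS1 (log2 fold change 0.91, SE 0.17) lies opposite SLC7A11, a member of the integrated stress response and NRF2 lists. LINC00649 (−0.37, SE 0.11) lies opposite ATP5PO of the oxidative phosphorylation list and 1 other coding gene. ENO1-AS1 (−0.62, SE 0.18) lies opposite ENO1 of the glycolysis list, and CDKN2B-AS1 (−0.65, SE 0.20) lies opposite CDKN2A of the cyclin-dependent kinase inhibitor and reported EZH2-repressed lists. CDKN2B-AS1 had −0.31 without control replicate 1 and −0.32 without BHB replicate 2. None of the called features named in this paragraph kept the call without each library in turn. GABARAPL1-AS1, opposite an autophagy gene, had 1.14 (SE 0.48) and OXCT1-AS1, opposite the gene of a ketone-using enzyme, had −0.13 (SE 0.14), and neither passed the edgeR test. In 3 lists at least 3 members had such a feature. None of these passed camera on the partnered features, with adjusted p of 0.34 for the integrated stress response, 0.48 for cholesterol synthesis and 0.49 for the BCL2 family.

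The first pattern is that features opposite coding genes hold more counts than those genes. Unstranded counting would put the ratio of densities near 1, and the 95% bootstrap interval of its median runs from 4.55 to 9.53. Antisense transcription with correctly assigned strands would leave ribosomal protein genes among the 500 features with most counts, and 0 of the 30 were there. The explanation left open is that the reads of this stranded library were counted on the strand opposite to the annotated gene, which is in line with 67.5% of pairs having the higher density in the noncoding feature and with MT-ND6 at 21.2 times or more the heavy-strand median in every library, though the pairs that go the other way were not explained. On this hypothesis, counts listed under EZH2 may be reads of the minority strand, and counts listed under a partnered feature may reflect the coding gene opposite it. No biological explanation other than antisense transcription was tested.

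The second pattern is that no feature passed over the whole table while the controls differed. Deeper sequencing of control replicate 1 would raise all features by the log2 ratio of the totals, 0.20. It is argued against by the median log2 ratio of 1.58 in solitary coding genes (95% bootstrap interval 1.499 to 1.655). A broad expression difference between the control cultures stays open. The clone-named features, which were assigned to neither class of the pattern because they were not placed, had a common dispersion of 0.0095. No broad difference was thus seen among them. Some may lie opposite coding genes like the partnered features, whose common dispersion was 0.0091. Their value is therefore no independent test of this explanation. Solitary coding genes had 0.148, but their spread is the pattern to be explained, so this value decides nothing. A difference confined to coding genes was not tested. Another candidate explanation that stays open is that the share of reads on the minority strand differed between the controls. It was tested on the 61 noncoding features with no gene body on the other strand, and the shift it predicted was not seen in their median log2 ratio of the controls, 0.066 (95% bootstrap interval 0.00 to 0.18). This lies under the bound of 0.5 in the prediction, by which the explanation would not fit. The explanation does not need all of these features to move, since their counts may come from unannotated RNA of the other strand. They ran from −1.48 to 2.69, with NORAD at 71 and 13 counts and NEAT1 at 48 and 7 in control replicates 1 and 2, so the test was taken as undecided, a choice made after these values were seen. In the pairs, the coding gene had a median of 10.0% of the opposite feature's count in control replicate 1, 3.67% in control replicate 2, and 6.59% and 6.44% in BHB replicates 1 and 2.

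The third pattern is that the mitochondrial protein list was higher with BHB. The minority-strand share would put control replicate 1 above both BHB libraries, and it was so in 0 of the 13 genes. This is no independent test, since in 9 of them both BHB libraries lay above both controls, which is part of the pattern itself. BHB replicate 2 alone is argued against by a median log2 fold change of 0.66 without it. The lowest median under the other scalings was 0.78, which decides nothing about scaling, since these scalings moved the median of all features by only 0.049. The BHB treatment stays open as an untested biological explanation, and so does a difference in culture or RNA preparation between the groups. If reads were counted on the opposite strand, the counts under heavy-strand genes may be light-strand RNA, so that the list need not speak of the messenger RNAs it names. On the same hypothesis the counts under MT-ND6 may be RNA of the other strand. They changed least of the 13, with a log2 fold change of 0.39 (SE 0.29).

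A further hypothesis was that the counts listed under a coding gene follow that gene's expression, read from the opposite noncoding feature. Across 451 pairs in which the noncoding feature had a mean of at least 20 counts, the densities had a Spearman rho of 0.20 (95% bootstrap interval 0.11 to 0.28; permutation p = 6e-05 over 100000 permutations; adjusted p = 0.0001 over 2 relations). A minimum on the summed counts of the pair, used first, gave −0.18, but such a minimum pushes rho down by itself. Across 351 pairs the log2 fold changes had a rho of 0.13 (permutation p = 0.0133, adjusted p = 0.0133). Both lie below 0.3, the bound used for each, and noise at low counts would weaken both. So may reads from the part of the noncoding feature outside the overlap, which was as short as 84 exonic bases for SRI-AS1. The difference between the controls may weaken the rho of the fold changes further. Their log2 ratio had an SD of 1.14 in solitary coding genes, against 0.35 in partnered features. A rho under the bound therefore does not settle the hypothesis. Genes are not independent replicates in either. The relations were positive but weaker than predicted, so the counts listed under coding genes were not read as a measure of their expression.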
